A study of Mus musculus with 24 samples.

How the data were processed

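RNA sequencing measured transcripts in CD11c-positive dendritic cells purified from the mesenteric lymph nodes of mice that carried MC38 colon tumours. Wild-type and Myd88 knockout mice received control IgG, an antibody against PD-1, the oral bacterium LGG (Lactobacillus rhamnosus GG) or the antibody and LGG together, which gives 8 groups of 3 libraries and 24 libraries in all. Per the labels' protocols, female C57BL/6 mice of 6 to 8 weeks were injected under the skin with 1000000 tumour cells. Treatment began after 7 to 10 days, when tumours reached 100 mm3, at 2 doses a week of 200 ug of antibody per mouse for 2 to 3 weeks. No antibody dose is recorded for the groups with LGG alone, so LGG against IgG also differs in the antibody recorded. The labels do not say that the replicates of a group come from separate animals, so the p-values may measure technical spread only.

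The authors deposited 1 table of normalised signal, in which each value is a read count divided by a factor for its library. Per the submitters' processing notes, reads were aligned with STAR 2.4.0 to genome build mm10, counted per gene with HTSeq 0.6.1 and normalised with DESeq2, whose version is not stated. The table lists 12767 genes with a lowest mean of 9.57. Each library's values are whole multiples of 1 step. Dividing by that step returned whole reads for 100% of the values within a tolerance of 0.001, and these whole reads served the count-based tests. Reads assigned to the listed genes ranged from 24531528 to 49272593 per library. Genes that the table does not list add nothing to these totals. Gene coordinates, transcript lengths and GC content come from an annotation of the same build. Of the genes, 12765 matched it by identifier and 12759 had a length.

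From the deposited values, log2(value + 1) was computed for the 12749 genes with a mean of at least 10. The main test was limma 3.58.1 in R 4.3.3: a linear model with 1 mean per group over all 24 libraries, with empirical Bayes moderation that allows a mean-variance trend and outlying variances. Two-sided p-values were adjusted by Benjamini and Hochberg within each comparison, and a gene was called below an adjusted p of 0.05. Errors after a log2 fold change are standard errors of that model, and errors after a mean are standard deviations over 3 libraries. The planned comparisons number 14. In each genotype they set every treatment against IgG and the combination against anti-PD-1 alone. They also set knockout against wild type in IgG and over the mean of the 4 treatments, and compare each treatment effect between the genotypes (an interaction). A further 2 comparisons, the combination against LGG alone in each genotype, were added after the data were examined. The planned comparisons, the gene lists, the main test, the rule for named genes and all but 2 of the settings listed last were chosen before the data were examined, except the method of the array weights. Its default did not converge on these data, and a gene-by-gene estimate took its place. A list of GM-CSF culture genes and some tests of the closing section were also chosen after the data were examined.

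Of 32 fixed gene lists, 30 had at least 3 listed members and were tested with camera at a preset correlation of 0.01, adjusted over the 30 lists of each comparison. Each call was repeated with a correlation estimated from the data. The lists cover interferon and inflammatory responses, costimulation, antigen presentation, metabolism, cell cycle and stress, and markers of dendritic cell subsets and of other cell types.

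Named genes follow a rule. For each comparison it takes up to 8 called genes with the largest rise and 8 with the largest fall. Their mean is at least 20 in the higher group, and the libraries of the groups compared do not overlap, which chance gives in 10% of genes for 3 libraries against 3. Predicted genes and antigen receptor segments were passed over. Where fewer than 5 genes pass, the 5 with the smallest p are taken. It adds up to 4 members with the smallest p from each list described, and a fixed set of genes that the design asks about (Myd88, interferon, cytokine, costimulation and sensing genes). Of that set, Ifna4 is not listed in the table analysed here. A fold against a group with reads in no library is a lower bound against a floor of 3 reads over the group. Such floors cover counting error only.

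Alternatives were a pseudocount of 8, no filter on low values, TMM scaling, array weights, only the libraries compared in the fit, a replicate block, edgeR 4.0.16 and DESeq2 1.42.0 on whole reads, an estimated correlation for the lists, and each library left out in turn. Another 2 were chosen after seeing the data: 3 libraries that stand apart left out, and a trend with transcript length and GC content removed from each library. Without the 3 libraries, knockout anti-PD-1 keeps replicate 1 only and knockout LGG keeps replicates 1 and 3. Gene counts from that fit are therefore not given for comparisons that use knockout anti-PD-1. The test was checked on simulated counts for the wild-type LGG against IgG comparison. Of planted genes that were tested, it recovered 22 of 66 at 1.5-fold, 50 of 63 at 2-fold and 65 of 65 at 4-fold, and it called 6 of 12306 unchanged genes. Every group was simulated at the spread estimated over all 24 libraries, whose common biological coefficient of variation was 0.17. The groups themselves ranged from 0.033 to 0.38. The check therefore does not cover their unequal spread.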

Results

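The data are messenger RNA profiles of 24 dendritic cell libraries, 3 in each of 8 groups formed by 2 genotypes and 4 treatments. The genotypes are wild type and knockout of Myd88. Mice received control IgG, an antibody to PD-1, the bacterium LGG, or both of these at once, called the combination below. Reads assigned to the listed genes ranged from 24531528 in wild-type IgG replicate 3 to 49272593 in knockout IgG replicate 1. At this depth a gene at the lowest listed mean of 9.57 rests on few reads per library, and its fold changes are the least precise. The design asks what LGG and anti-PD-1, alone and together, do to the transcripts of these cells, and how far each effect depends on Myd88.

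The first principal component held 64.3% of the variance and set all 6 wild-type libraries with LGG, at 104.9 to 108.8, apart from all others. The 6 libraries labelled knockout with LGG lay from -27.9 to -14.1 and the 6 without it from -77.4 to -61.9. Wild-type libraries without LGG lay from -18.1 to -6.8. Replicates lay close together in most groups, with a biological coefficient of variation of 0.051 to 0.089 in the wild-type groups. Groups labelled knockout had 0.082 in IgG, 0.38 in anti-PD-1, 0.25 in LGG and 0.033 in the combination. Anti-PD-1 replicates 2 and 3 and LGG replicate 2 of the libraries labelled knockout stood apart from their groups on the second component, at -16.5, 51.3 and 46. Anti-PD-1 replicate 1, at 25.1, lay between the other 2 of its group.

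**Figure D1:**
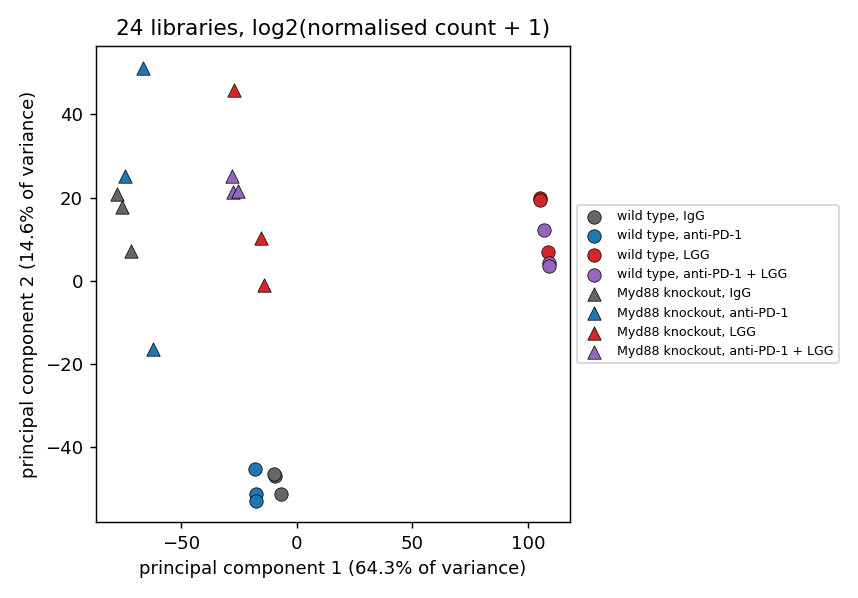
Each point is 1 of the 24 libraries, placed by its scores (no unit) on the first principal component (64.3% of the variance) and the second (14.6%). Circles are wild type and triangles are labelled knockout, and colours give the treatment. The 6 wild-type libraries with LGG lie at 104.9 or above on the first component, and the 3 libraries labelled knockout and treated with anti-PD-1 are spread from -16.5 to 51.3 on the second.

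Myd88 (chromosome 9, 119335934 to 119341411) encodes the adaptor used by most Toll-like receptors and by interleukin-1 receptors. It was counted in every library, at 1723 to 2232 normalised counts in the 12 wild-type libraries and 697.3 to 1837 in the 12 labelled knockout. The highest of the latter, anti-PD-1 replicate 3, lay within the wild-type range. Over the mean of the 4 treatments Myd88 was lower in the libraries labelled knockout by a log2 difference of -0.93 ± 0.09 (adjusted p = 3.12e-08, limma). A count over the whole gene cannot show whether an exon is deleted, so the genotype is given below as labelled.

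LGG against IgG in wild-type libraries asks how the transcripts of the purified cells differ with the bacterium where Myd88 is present. The values do not separate a change within cells from a change in the mixture of cells. Inflammatory cytokine genes rose, beside genes of other kinds (n = 3 per group). Il1b went from 637.1 ± 59.2 to 73942 ± 5396 normalised counts, and Tnf, which encodes the cytokine TNF, from 641.1 ± 49.7 to 63620.2 ± 3564. Il12b and Il12a, the subunits of interleukin-12, rose by 6.76 ± 0.39 and 8.52 ± 0.49 on the log2 scale, and Il6 by 4.43 ± 0.08. Nos2, the inducible nitric oxide synthase, rose 136-fold (log2 7.09 ± 0.08), and Csf3, which encodes G-CSF, went from 1.05 to 9549 normalised counts. Hamp, which encodes the iron hormone hepcidin, rose by 8.85 ± 0.61 and Vnn3 by 7.02 ± 0.59, and Barx1, a homeobox gene, went from 0.903 to 204.9 normalised counts. Mrc1, the macrophage mannose receptor, fell by 7.65 ± 0.21 on the log2 scale, Arg1 (arginase) fell by 5.77 ± 0.15 and the chemokine receptor gene Ccr2 fell by 5.44 ± 0.11. The amino acid transporter gene Slc36a2 and the receptor gene Tlr8 also fell, with log2 changes of -8.83 ± 0.26 and -6.65 ± 1.04. All these genes had an adjusted p of 1.79e-05 or lower.

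The fixed lists moved with them. Of 28 measured inflammatory and NF-kB target genes, 28 rose, 0 fell and 0 did not pass, with 28 called when adjusted over the list alone (median log2 3.01, camera adjusted p = 2.55e-20). Examples beside the cytokines above are Il1a at 4.63 ± 0.09, Cxcl1, a neutrophil chemokine, at 5.79 ± 0.11, and Il10 at 6.46 ± 0.46. Of 37 genes of the type I interferon response, 37 rose, 0 fell and 0 did not pass, with 37 called when adjusted over the list alone (median 2.09, adjusted p = 6.56e-20). Isg15, a ubiquitin-like modifier, rose by 4.70 ± 0.20, Rsad2 (viperin) by 3.93 ± 0.13 and Irf7, a regulator of interferon genes, by 3.73 ± 0.17. Ifnb1, which encodes interferon beta, rose from 1.42 ± 0.735 to 64.4 ± 10.3 normalised counts (log2 4.79 ± 0.46). Of 20 interferon-gamma response genes 17 rose, 0 fell and 3 did not pass, with 17 called when adjusted over the list alone (adjusted p = 1.94e-08), among them Cxcl10 at 4.65 ± 0.16 and Cxcl9 at 3.70 ± 0.53.

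Genes of dendritic cell maturation rose as well. The list of migratory or mature dendritic cell genes had 17 of 19 members rise, 0 fall and 2 not pass (camera adjusted p = 2.82e-11), and adjusted over the list alone 17 rose and 1 fell. Ccr7, the lymph node homing receptor, went from 6153 ± 145 to 76466 ± 5363 normalised counts, and Fscn1, an actin bundler, rose by 4.24 ± 0.16. Of 17 costimulation and checkpoint genes 12 rose, 2 fell and 3 did not pass, the same counts as when adjusted over the list alone (adjusted p = 1.75e-05). Cd40 rose by 5.53 ± 0.20, Cd86 by 3.42 ± 0.07, Cd80 by 3.19 ± 0.09 and Cd274, which encodes PD-L1, by 1.86 ± 0.15, and Vsir, an inhibitory ligand gene, fell by 2.15 ± 0.06. Of 22 genes of MHC class I presentation 16 rose, 3 fell and 3 did not pass, also adjusted over the list alone. Its adjusted p of 0.000719 became an adjusted p = 0.34 with an estimated correlation. Of 16 genes of the tolerogenic list 11 rose, 3 fell and 2 did not pass, also adjusted over the list alone (adjusted p = 0.0153, and adjusted p = 0.064 with an estimated correlation). Its members include Aldh1a2, a retinoic acid synthesis gene, at 1.72 ± 0.11.

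Macrophage and cell cycle genes fell. Of 19 macrophage and monocyte genes 3 rose, 14 fell and 2 did not pass, also adjusted over the list alone (adjusted p = 7.54e-05). Csf1r, the receptor of the macrophage growth factor, changed by -2.37 ± 0.06 and Fcgr1 by -2.80 ± 0.12. Of 26 cell cycle genes 0 rose, 24 fell and 2 did not pass, also adjusted over the list alone (adjusted p = 7.27e-11), including the mitotic genes Bub1b at -2.43 ± 0.10 and Aurkb at -2.01 ± 0.08. Of 15 cDC2 markers 4 rose, 10 fell and 1 did not pass, also adjusted over the list alone (adjusted p = 0.00274, and adjusted p = 0.097 with an estimated correlation), including the lectin gene Mgl2 at -4.01 ± 0.10. Among sensors, Tlr2, a receptor for bacterial lipoproteins, rose by 1.75 ± 0.06 and Tbk1 by 0.47 ± 0.13. Cgas at -0.08 ± 0.34, Tmem173, which encodes STING, at -0.08 ± 0.09 and Myd88 at 0.14 ± 0.19 did not pass. In all, limma called 7081 of 12749 genes, of which 3488 rose and 3593 fell, and 3198 of them changed over 2-fold. Of 30 lists 13 were called, 8 up and 5 down, and 8 of these also with an estimated correlation.

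**Figure D2:**
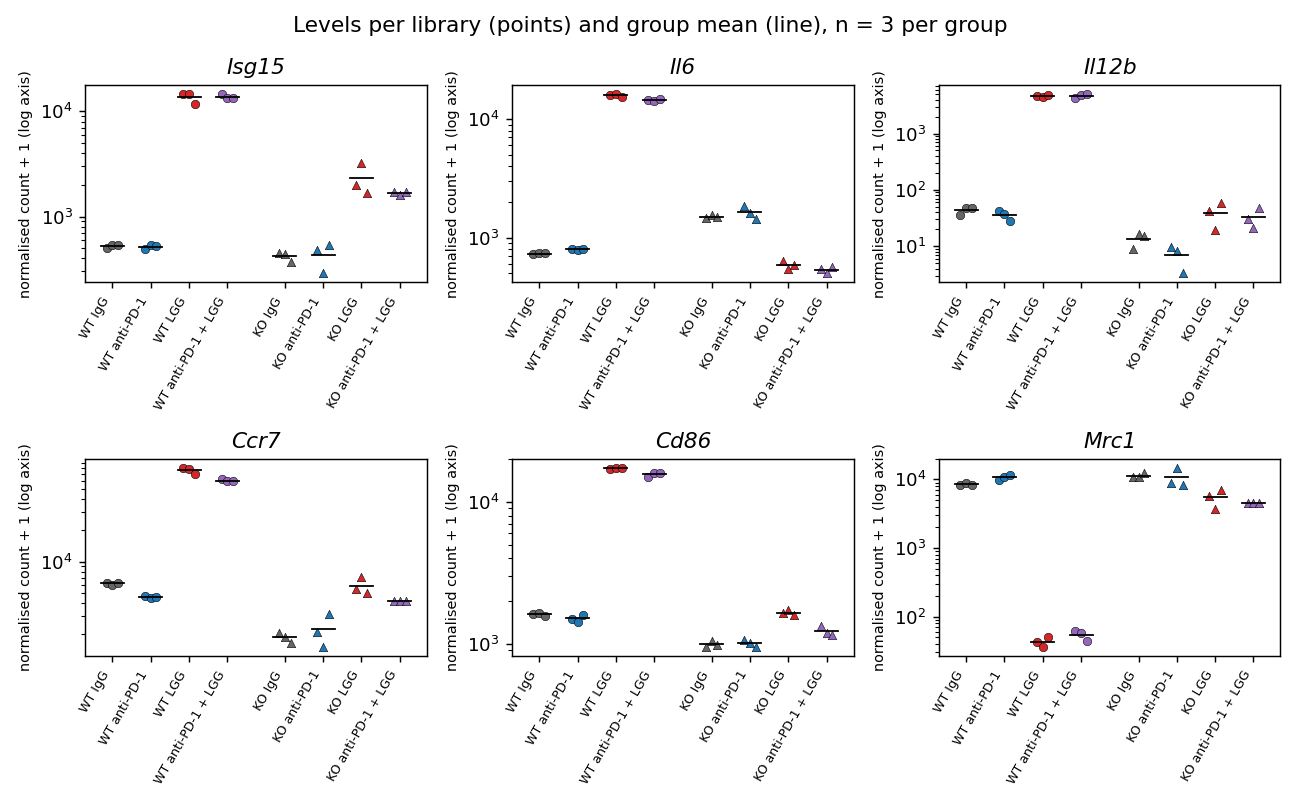
Normalised counts plus 1 on log axes for 6 genes in the 8 groups of 3 libraries each. Points are libraries, with circles for wild type (WT) and triangles for labelled knockout (KO), and lines are group means. Il6 rises from 732.7 to 15839 with LGG in wild type and falls from 1502 to 590.2 in the libraries labelled knockout.

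LGG against IgG in the libraries labelled knockout asks which part of the response occurs in that genotype. Clec4e, a receptor for microbial glycolipids, rose from 621.1 ± 23.4 to 14137 ± 205 normalised counts (n = 3 per group), and Il1f9, an interleukin-1 family cytokine, rose by 4.68 ± 0.15 on the log2 scale. Cyp26b1, which degrades retinoic acid, rose by 4.66 ± 0.20, the glutathione transferase gene Gsta2 by 4.27 ± 0.40, Ptpn14 by 4.14 ± 0.34, Nos2 by 3.89 ± 0.08 and Lox, which crosslinks collagen, by 3.76 ± 0.32. The largest falls were in the matrix gene Matn2 at -3.58 ± 0.42, the transporter gene Slco2b1 at -3.24 ± 0.31, Foxd1 at -3.05 ± 0.40, Fam20a at -2.81 ± 0.37 and G0s2, an inhibitor of lipolysis, at -2.71 ± 0.36. Il6 fell from 1502 ± 54.4 to 590.2 ± 45.6 normalised counts, a log2 change of -1.35 ± 0.08. All these genes had an adjusted p of 8.07e-06 or lower.

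Interferon response genes rose in these libraries too. Of 37 type I genes 33 rose, 0 fell and 4 did not pass, with 35 called when adjusted over the list alone (median log2 1.34, camera adjusted p = 6.43e-27). Rsad2 rose by 3.46 ± 0.13, Irf7 by 2.54 ± 0.17 and Oasl2 by 1.85 ± 0.06, and Isg15 went from 419.8 ± 44.8 to 2302 ± 842.1 normalised counts. Ifnb1 rose from 1.04 ± 0.984 to 19.3 ± 10.2 normalised counts (log2 3.33 ± 0.46). Of 20 interferon-gamma response genes 14 rose, 0 fell and 6 did not pass, also adjusted over the list alone (adjusted p = 1.03e-10), with Cxcl10 at 2.87 ± 0.16, and Cxcl9 at 0.62 ± 0.53 did not pass. Of 28 inflammatory genes 20 rose, 2 fell and 6 did not pass, also adjusted over the list alone (adjusted p = 4.87e-10), with Tnf at 2.87 ± 0.15. The migratory dendritic cell list had 14 of 19 genes rise, 1 fall and 4 not pass, also adjusted over the list alone (adjusted p = 5.7e-08), with Fscn1 at 2.42 ± 0.16 and Ccr7 at 1.64 ± 0.17. Of 17 costimulation genes 11 rose, 2 fell and 4 did not pass, also adjusted over the list alone (adjusted p = 0.00243), with Cd40 at 2.52 ± 0.20, Cd274 at 0.80 ± 0.15, Cd86 at 0.75 ± 0.07 and Cd80 at 0.67 ± 0.09. Tlr2 rose by 1.69 ± 0.06.

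Markers of lymphocytes moved with the interferon genes in the libraries labelled knockout. Of 20 T cell markers 20 rose, 0 fell and 0 did not pass, with 20 called when adjusted over the list alone (median 1.84, adjusted p = 6.4e-13). Cd3e, a chain of the T cell receptor complex, went from 47.6 ± 7.23 to 290.5 ± 50.9 normalised counts. Of 11 natural killer and cytotoxic markers 10 rose, 0 fell and 1 did not pass, also adjusted over the list alone (adjusted p = 3.81e-08), with Gzmb (granzyme B) at 2.13 ± 0.08 and Prf1 (perforin) at 2.47 ± 0.22. Of 13 B cell markers 9 rose, 0 fell and 4 did not pass, also adjusted over the list alone (adjusted p = 0.000753), with Cd79a at 2.26 ± 0.38. Of 26 cell cycle genes 0 rose, 24 fell and 2 did not pass, also adjusted over the list alone (adjusted p = 2.94e-16), with Ccnb2, a mitotic cyclin gene, at -1.22 ± 0.09. Of 16 glycolysis genes 6 rose, 0 fell and 10 did not pass (adjusted p = 0.00191), and adjusted over the list alone 9 rose, with the glucose transporter gene Slc2a1 at 0.59 ± 0.05. Limma called 4108 of 12749 genes, of which 2304 rose and 1804 fell. Of 30 lists 17 were called, 12 up and 5 down, and 10 of these also with an estimated correlation. With anti-PD-1 replicates 2 and 3 and LGG replicate 2 of the libraries labelled knockout left out, which was chosen after seeing the data, the count was 7830, with array weights it was 9068 and in a fit of the 6 libraries alone 2677. Array weights were 8.4, 0.084 and 0.4 for LGG replicates 1, 2 and 3, so the weighted LGG mean rests mostly on 1 library.

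**Figure D3:**
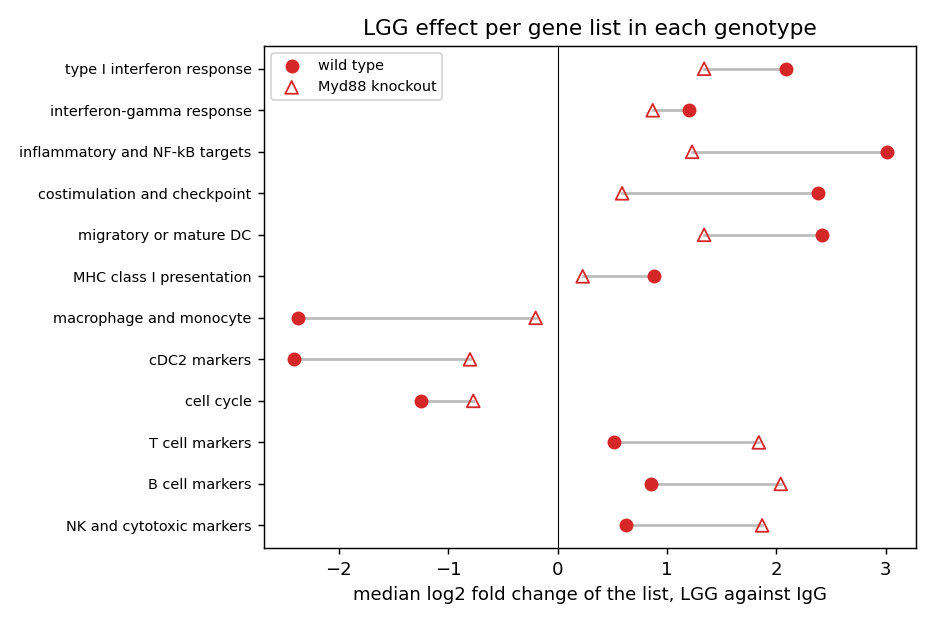
Median log2 fold change of each list's genes, LGG against IgG, with filled circles for wild type and open triangles for the libraries labelled knockout. The inflammatory list has 3.01 in wild type and 1.23 in the libraries labelled knockout, the T cell list 0.52 and 1.84. T, B and natural killer cell lists in wild type and the macrophage list in the libraries labelled knockout did not pass the list test.

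The difference of the LGG effect between the genotypes (knockout minus wild type, n = 3 per group) compares the responses directly. Y-linked genes differ between the genotypes in the same libraries, so it is not separated from what goes with them. A negative difference is a smaller rise, or a larger fall, in the libraries labelled knockout. Hamp differed by -8.11 ± 0.86 on the log2 scale, Il12a by -6.15 ± 0.70, Il6 by -5.78 ± 0.11, Cxcl1 by -5.59 ± 0.16, Il12b by -5.30 ± 0.55, Il1b by -5.24 ± 0.17 and Tnf by -3.77 ± 0.22. Costimulation genes Cd86 at -2.67 ± 0.09 and Cd80 at -2.52 ± 0.13, Ccr7 at -1.99 ± 0.24 and Isg15 at -2.31 ± 0.29 also differed. Positive differences were seen in Slc36a2 at 7.87 ± 0.36, Mrc1 at 6.55 ± 0.29 and Ccr2 at 4.64 ± 0.15, which fell in both genotypes, and in Csf1r at 2.71 ± 0.09, which fell in wild type and rose by 0.34 ± 0.06 in the libraries labelled knockout. Tlr2 at -0.06 ± 0.08 (adjusted p = 0.607) and Ifnb1 at -1.45 ± 0.65 (adjusted p = 0.0948) did not pass. Ifnb1 passed at -1.9 without IgG replicate 3 and at -1.83 without LGG replicate 2 of the libraries labelled knockout.

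By list, the inflammatory genes had a lower response in the libraries labelled knockout in 25 of 28, a higher one in 0 and no call in 3, also adjusted over the list alone (median -2.44, camera adjusted p = 5.43e-19). Type I interferon genes had 21 of 37 lower, 4 higher and 12 not past the test, and adjusted over the list alone 24 lower and 4 higher (median -0.64, adjusted p = 3.41e-05). Costimulation genes had 11 of 17 lower, 1 higher and 5 not past, also adjusted over the list alone (median -1.67, adjusted p = 8.38e-06). Migratory dendritic cell genes had 14 of 19 lower, 0 higher and 5 not past, with 15 lower when adjusted over the list alone (median -1.55, adjusted p = 1.6e-10). Macrophage genes had 12 of 19 higher, 2 lower and 5 not past, with 14 higher and 2 lower when adjusted over the list alone (median 1.86, adjusted p = 1.42e-05). T cell markers had 12 of 20 higher, 0 lower and 8 not past, with 14 higher when adjusted over the list alone (median 1.45, adjusted p = 1.42e-05). Their level stayed lower in the libraries labelled knockout. The median expression percentile among all genes was 17.7 under IgG and 32.1 with LGG, against 48 and 54.2 in wild type. Limma called 4449 genes, 2487 higher and 1962 lower, and 15 of 30 lists, 9 of these also with an estimated correlation. The gene count was 8949 with array weights and 8010 without the 3 libraries that stand apart. Across 12749 genes, which are not independent replicates, the LGG effects of the genotypes had a Pearson r of 0.567 and a slope through the origin of 0.33. They share no library. Genes that rose in both numbered 1501, against 630 for independent lists, and 1283 fell in both, against 508.

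Anti-PD-1 against IgG asks what the antibody alone does. In wild-type libraries Slc30a1, a zinc exporter gene, rose from 635.7 ± 24.8 to 844 ± 12 normalised counts (n = 3 per group). Cacnb3, a calcium channel subunit gene, fell by 0.48 ± 0.08 on the log2 scale, the GTPase gene Gimap4 by 0.41 ± 0.07 and Arc, an activity-regulated cytoskeletal gene of neurons and migratory dendritic cells, by 0.58 ± 0.10. These 4 genes, each with an adjusted p of 0.0481, were the only calls of limma, against 9 by edgeR and 207 by DESeq2, with 1028 genes at an unadjusted p under 0.05. Lists of lymphocyte markers had negative medians. Of 20 T cell markers 0 rose, 0 fell and 20 did not pass, and adjusted over the list alone 5 fell (median -0.44, camera adjusted p = 1.87e-06, and adjusted p = 0.051 with an estimated correlation). The 19 migratory dendritic cell genes had 0 rise, 1 fall and 18 not pass, with 2 lower when adjusted over the list alone (median -0.25, adjusted p = 3.56e-06, and adjusted p = 0.051 with an estimated correlation). Of 30 lists 10 were called and 0 of these with an estimated correlation. Leaving out any of the IgG libraries, or anti-PD-1 replicate 2 or 3, lowered the limma count to 0, and leaving out anti-PD-1 replicate 1 gave 3, against the 9 edgeR and 207 DESeq2 calls with all libraries. The limma count was higher in a fit of the 6 libraries alone (1760), with array weights (3056) and with the 3 libraries labelled knockout that stand apart left out (1079). The variance of the main fit takes in the spread of the libraries labelled knockout. Their biological coefficient of variation was 0.38 in anti-PD-1 and 0.25 in LGG, against 0.051 and 0.058 in the wild-type groups compared. Genes that did not pass here are therefore not shown to be unchanged.

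In the libraries labelled knockout, anti-PD-1 lowered Serpinb9b, a serine protease inhibitor gene, from 435.5 ± 23.3 to 86.4 ± 22.7 normalised counts (log2 -2.35 ± 0.14, n = 3 per group). The alarmin gene Il33 fell by 1.76 ± 0.16 on the log2 scale, Eef1a2 by 1.75 ± 0.24 and the carbonic anhydrase gene Car2 by 1.22 ± 0.14, and Fst, an activin inhibitor gene, went from 116.3 ± 11.7 to 40.5 ± 5.76 normalised counts. Cd3e rose by 0.97 ± 0.18, from 47.6 ± 7.23 to 97.7 ± 32.9 normalised counts. Among the largest rises were Gp9 at 1.44 ± 0.34 and Gp1bb at 1.39 ± 0.35, which encode parts of a platelet receptor, Cavin2 at 1.54 ± 0.31 and Pear1, a platelet receptor gene, which went from 20.4 ± 2.57 to 62 ± 38.4 normalised counts. Their calls were lost without single libraries: IgG replicate 1 (Cavin2 1.43, Gp9 1.51, Gp1bb 1.49), IgG replicate 2 (Cavin2 1.36, Gp9 1.33, Gp1bb 1.27, Pear1 1.26), IgG replicate 3 (Gp9 1.46, Gp1bb 1.42), anti-PD-1 replicate 1 (Gp9 1.2) and anti-PD-1 replicate 3 (Gp9 1.43, Gp1bb 0.951). Without the 3 libraries that stand apart, which leaves anti-PD-1 replicate 1 alone in its group, the log2 changes were 1.47 in Cavin2 and 0.425 in Pear1. Gp9 and Gp1bb also lost their calls with a pseudocount of 8 (0.937 and 1.17) and with edgeR (1.54 in both). The call of Gp9 was lost with the length and GC trend removed (1.14) and that of Gp1bb with a replicate block (1.39). Of 13 B cell markers 2 rose, 0 fell and 11 did not pass, with 6 higher when adjusted over the list alone (camera adjusted p = 1.98e-05, and adjusted p = 0.068 with an estimated correlation). Of 20 T cell markers 4 rose, 0 fell and 16 did not pass, with 9 higher and 1 lower when adjusted over the list alone (adjusted p = 3.17e-05, and adjusted p = 0.12 with an estimated correlation). Limma called 229 genes, 139 up and 90 down, and 7 of 30 lists, 0 of these with an estimated correlation. Replicates 2 and 3 of this group stood apart, and the count was 4581 without anti-PD-1 replicate 2, 745 without replicate 1, 108 without replicate 3, and 88, 74 and 121 without IgG replicates 1, 2 and 3. The count was 3053 with array weights, which were 2.3, 0.058 and 0.061 for anti-PD-1 replicates 1, 2 and 3. Leaving out the 3 libraries that stand apart leaves 1 library in this group, so no count is given for it. A fit of the 6 libraries alone called 0 genes with limma, against 192 by edgeR and 602 by DESeq2 over all libraries and 1992 at an unadjusted p under 0.05.

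The anti-PD-1 effect differed between the genotypes (knockout minus wild type) in 242 genes, 167 higher and 75 lower. Serpinb9b differed by -2.24 ± 0.20 on the log2 scale, Fst by -1.98 ± 0.31 and Il33 by -1.75 ± 0.23 (adjusted p of 0.00319 or lower, limma, n = 3 per group). Of 13 B cell markers 4 were higher, 0 lower and 9 not past, with 6 higher when adjusted over the list alone (median 1.36, camera adjusted p = 2.16e-06). Of 20 T cell markers 4 were higher, 0 lower and 16 not past, with 14 higher and 1 lower when adjusted over the list alone (median 0.97, adjusted p = 1.12e-07). Of 11 cytotoxic markers 2 were higher, 0 lower and 9 not past, with 6 higher when adjusted over the list alone (median 0.77, adjusted p = 2.16e-06). In all 5 of 30 lists were called, 3 of these also with an estimated correlation. Without anti-PD-1 replicate 2 of the libraries labelled knockout the count was 3830. It was 5112 with array weights and 1 in a fit of the libraries compared.

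The combination against IgG asks what LGG and the antibody do together, and against anti-PD-1 alone what LGG adds in the presence of the antibody. Against IgG in wild type, Nos2 rose by 7.47 ± 0.08 on the log2 scale, Ptges, a prostaglandin E synthase gene, by 7.16 ± 0.15, the interferon-inducible gene Ifi205 by 6.96 ± 0.20, Il12b by 6.76 ± 0.39 and Isg15 by 4.72 ± 0.20 (n = 3 per group). Mrc1 fell by 7.30 ± 0.21 and the lectin gene Clec4b1 changed by -6.40 ± 0.27. Limma called 7010 genes, 3408 up and 3602 down, and 13 of 30 lists, 8 of these also with an estimated correlation. The type I interferon list again had 37 of 37 genes rise, 0 fall and 0 not pass, also adjusted over the list alone (camera adjusted p = 2e-21). Against anti-PD-1 in wild type, Il1b rose by 7.18 ± 0.12, Il12b by 7.04 ± 0.39, Cd40 by 5.69 ± 0.20 and Cd86 by 3.38 ± 0.07, and Mrc1 fell by 7.64 ± 0.21. Csf3 was at 0 in all 3 anti-PD-1 libraries and at 8032 ± 619 with LGG added, at least 9333-fold higher against a floor of 3 reads over the group. Limma called 7247 genes, 3537 up and 3710 down, and 12 of 30 lists, 8 of these also with an estimated correlation. Across 12749 genes, this effect and that of LGG against IgG, which share no library, had a Pearson r of 0.967 and a slope of 1.01.

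In the libraries labelled knockout, the combination against IgG raised Cyp26b1 by 4.81 ± 0.20 on the log2 scale, Rtn4rl2 by 4.59 ± 0.20, Clec4e by 4.31 ± 0.08 and Isg15 by 1.99 ± 0.20 (n = 3 per group). Il6 fell by 1.49 ± 0.08, Retnla, a marker of alternatively activated macrophages, by 2.20 ± 0.41, and Id1 by 2.12 ± 0.26. Limma called 4267 genes, 2431 up and 1836 down, and 15 of 30 lists, 7 of these also with an estimated correlation. The gene count was 7369 in a fit of the 6 libraries alone, 8210 with array weights and 7299 without the 3 libraries that stand apart. Against anti-PD-1, Rtn4rl2 rose by 5.25 ± 0.20, Nos2 by 4.53 ± 0.08, Serpinb2 by 3.84 ± 0.21 and Isg15 by 2.00 ± 0.20, while Il6 fell by 1.60 ± 0.08 and the calprotectin gene S100a9 changed by -2.98 ± 0.36. Limma called 4673 genes, 2510 up and 2163 down, and 14 of 30 lists, 7 of these also with an estimated correlation. In this comparison 16 of 20 T cell markers rose, 0 fell and 4 did not pass, also adjusted over the list alone (camera adjusted p = 5.6e-06). Without anti-PD-1 replicate 2 the count was 7544, with array weights 8535 and in a fit of the 6 libraries alone 1245. Across 12749 genes, the effects of the combination against anti-PD-1 and of LGG against IgG had a Pearson r of 0.722 and a slope of 0.71 in these libraries. The effect of the combination differed between the genotypes in 4312 genes against IgG and in 4804 against anti-PD-1, with 13 lists called in each case and 6 of these also with an estimated correlation. Without anti-PD-1 replicate 2 of the libraries labelled knockout the latter count was 7264. With array weights these counts were 7952 and 8614. The count against IgG was 7388 in a fit of the groups compared and 7194 without the 3 libraries that stand apart.

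Knockout against wild type under IgG asks what the genotype does without LGG. The largest rises were Y-linked. Ddx3y was at 1.42 ± 0.735 normalised counts in wild type and 1621 ± 203 in the libraries labelled knockout (n = 3 per group), and Kdm5d was at 0 in all 3 wild-type libraries and 433.9 ± 76.9 in those labelled knockout, at least 421-fold higher. Elsewhere in the genome, Ch25h, which makes 25-hydroxycholesterol, rose by 3.57 ± 0.26 on the log2 scale, the carbonic anhydrase gene Car6 by 5.70 ± 0.60, Matn2 by 3.89 ± 0.42 and Il6 by 1.03 ± 0.08. The lymphocyte transcription factor gene Ikzf3 fell by 4.63 ± 0.23, the chemokine receptor gene Ccr8 by 4.61 ± 0.38 and Fscn1 by 2.90 ± 0.16. Adamts20 was at 37.2 ± 6.91 in wild type and at 0 in all 3 libraries labelled knockout, at least 46.8-fold lower.

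Lymphocyte and interferon-gamma genes were lower together in the libraries labelled knockout under IgG. Of 20 T cell markers 1 rose, 17 fell and 2 did not pass, with 1 higher and 19 lower when adjusted over the list alone (median -3.28, camera adjusted p = 2.37e-14), and Cd3e went from 821.1 ± 3.69 to 47.6 ± 7.23 normalised counts. Of 11 cytotoxic markers 0 rose, 11 fell and 0 did not pass, also adjusted over the list alone (adjusted p = 1.77e-12), with Gzmb at -3.77 ± 0.08. Of 13 B cell markers 0 rose, 10 fell and 3 did not pass, also adjusted over the list alone (adjusted p = 0.000244). Of 20 interferon-gamma response genes 0 rose, 18 fell and 2 did not pass, with 19 lower when adjusted over the list alone (adjusted p = 4.19e-13), with the GTPase genes Iigp1 at -3.72 ± 0.17 and Gbp4 at -2.43 ± 0.10. Of 37 type I interferon genes 1 rose, 26 fell and 10 did not pass, also adjusted over the list alone (adjusted p = 2.4e-07), with Irf7 at -1.58 ± 0.17. Of 19 migratory dendritic cell genes 3 rose, 13 fell and 3 did not pass, also adjusted over the list alone (adjusted p = 7.57e-05, and adjusted p = 0.051 with an estimated correlation), with Ccr7 at -1.73 ± 0.17. Limma called 4977 genes, 2429 higher and 2548 lower, and 13 of 30 lists, 7 of these also with an estimated correlation. The gene count was 7936 in a fit of the 6 libraries alone, 8769 with array weights and 8139 without the 3 libraries that stand apart. Myd88 itself fell by 0.58 ± 0.19 (adjusted p = 0.0185). Its call ended at -0.56 without wild-type IgG replicate 1 or 3 and at -0.50 without IgG replicate 3 of the libraries labelled knockout.

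Over the mean of the 4 treatments, knockout against wild type gave 9149 genes, 4747 higher and 4402 lower, at 12 libraries per genotype. Among the lower genes were Il10 at -4.90 ± 0.23 on the log2 scale, Il12b at -4.61 ± 0.19, Ifng, which encodes interferon gamma, at -4.29 ± 0.09, Ccr7 at -2.60 ± 0.09 and Cd86 at -2.09 ± 0.03. Among the higher were Rbp4, a retinol carrier gene, at 4.12 ± 0.10, the gluconeogenic gene Fbp1 at 4.07 ± 0.12 and Mrc1 at 3.43 ± 0.10. Of 28 inflammatory genes 0 rose, 27 fell and 1 did not pass, also adjusted over the list alone (camera adjusted p = 2.08e-12). These means include LGG and the combination, whose effects differed between the genotypes, so they do not describe each treatment. Under IgG, Il6 was at 1452 to 1560 normalised counts in the libraries labelled knockout against 721.7 to 741 in wild type. Tnf was at 481.7 to 593.6 against 585.1 to 680.3, and Mrc1 at 10738 to 12463 against 8297 to 8840. Of 16 glycolysis genes 12 rose, 1 fell and 3 did not pass, also adjusted over the list alone (adjusted p = 0.0203, and adjusted p = 0.097 with an estimated correlation). Of 30 lists 15 were called, 4 up and 11 down, and 10 of these also with an estimated correlation. The 4 Y-linked genes measured were at 190.7 normalised counts or more in the 12 libraries labelled knockout and at 6.43 or lower in the 12 wild-type libraries.

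The combination against LGG alone, added after the data were examined, asks what anti-PD-1 adds to LGG. In wild type 5 genes rose and 3 fell (n = 3 per group, limma), among them the thyroid hormone deiodinase gene Dio2 at 0.80 ± 0.12 on the log2 scale, with 11 calls by edgeR and 81 by DESeq2. The call of Dio2 ended without LGG replicate 1 (0.72), LGG replicate 2 (0.80) and combination replicate 3 (0.79). The type I interferon list had a median of 0.16 with 0 of 37 genes called and 3 higher when adjusted over the list alone (camera adjusted p = 6.06e-08). Of 30 lists 8 were called, 2 up and 6 down, and 2 of these also with an estimated correlation. With 827 genes at an unadjusted p under 0.05, the count of 8 fell to 1 without LGG replicate 1, 0 without LGG replicate 2, 4 without combination replicate 1 and 0 without combination replicate 3. It was 145 in a fit of the 6 libraries alone, 1095 with the 3 libraries labelled knockout that stand apart left out and 4680 with array weights. In the libraries labelled knockout 12 genes rose and 23 fell, among them the protease inhibitor gene Serpina3g at -0.81 ± 0.11, the kinase gene Camk4 at -0.84 ± 0.11 and Gzmb at -0.42 ± 0.08. Of 20 interferon-gamma response genes 0 rose, 2 fell and 18 did not pass, with 11 lower when adjusted over the list alone (median -0.34, adjusted p = 8.42e-17). The type I interferon list there had a median of -0.23 with 0 genes called, 2 lower when adjusted over the list alone and an adjusted p of 4.28e-14. T cell markers had a median of -0.36 with 0 of 20 called by limma, also adjusted over the list alone (adjusted p = 3.65e-07). Such falls were not particular to these lists: of 30 lists 15 were called, 1 up and 14 down, and 10 of these also with an estimated correlation. Without LGG replicate 2 the lists called numbered 11. LGG replicate 2 stood apart, with Isg15 at 3254 normalised counts against 1998 and 1654 in replicates 1 and 3. Limma called 47 genes without that library alone. Without the 3 libraries that stand apart it called 1437, and the anti-PD-1 libraries among those 3 are not in this comparison. The count of 35 was 15 and 20 without LGG replicates 1 and 3, and 19, 13 and 11 without combination replicates 1, 2 and 3, a fit of the 6 libraries alone called 0 and array weights 3656, against 55 by edgeR, 201 by DESeq2 and 879 at an unadjusted p under 0.05.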

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

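The depth test, the test of GM-CSF culture genes and the limit that leaves a mixture open were chosen after the result was seen. The mixture test in the LGG group was added after that in the anti-PD-1 group was seen and before its own value was. Also chosen after were the number of draws of the splits and the merging of mirror splits, set after first values that included a tie for anti-PD-1, and the other tests were planned.

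The effect of a treatment differed between the genotypes, by a test of the difference itself, in each planned treatment comparison. Anti-PD-1 against IgG differed in 242 genes and 5 gene lists, LGG against IgG in 4449 genes and 15 lists, the combination against IgG in 4312 genes and 13 lists, and the combination against anti-PD-1 in 4804 genes and 13 lists. Without anti-PD-1 replicate 2 of the libraries labelled knockout, the first gene count was 3830 and the last 7264. The first was also 688 without replicate 1 of that group, 143, 126 and 134 without IgG replicates 1, 2 and 3 of the libraries labelled knockout, 94, 98 and 93 without wild-type IgG replicates 1, 2 and 3, and 151, 96 and 94 without wild-type anti-PD-1 replicates 1, 2 and 3. Its list count was 8 without anti-PD-1 replicate 2 of the libraries labelled knockout.

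For LGG, the log2 differences (knockout minus wild type) were -8.11 in Hamp, -6.15 in Il12a, -5.78 in Il6, -5.59 in Cxcl1, -5.30 in Il12b, -5.24 in Il1b, -3.77 in Tnf, -2.67 in Cd86, -2.52 in Cd80, -2.31 in Isg15 and -1.99 in Ccr7. They were 7.87 in Slc36a2, 6.55 in Mrc1, 4.64 in Ccr2 and 2.71 in Csf1r. List medians differed by -2.44 for inflammatory, -1.67 for costimulation, -1.55 for migratory dendritic cell and -0.64 for type I interferon genes, and by 1.86 for macrophage and 1.45 for T cell genes. For anti-PD-1, Serpinb9b differed by -2.24, Fst by -1.98 and Il33 by -1.75, and list medians by 1.36 for B cell, 0.97 for T cell and 0.77 for cytotoxic markers.

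Other splits of the libraries were refitted for each difference. For anti-PD-1, 1 of 100 splits, the real one, gave as many as 242 genes, and the highest other gave 21, a share under 0.05. This rests on the anti-PD-1 group of the libraries labelled knockout, where 2 of 10 splits gave at least the real 229 genes and another split gave 4142, and a fit of the groups compared called 1 gene for the difference. For LGG, 10 of 100 splits gave at least the real 4449, the highest other 7077. For the combination 8 of 100 gave at least 4312 against IgG (highest other 7136), and 10 of 100 at least 4804 against anti-PD-1 (highest other 7317). All 9, 7 and 9 of the other splits as large keep the groups of 1 genotype undivided and so hold its real treatment difference, so these counts do not decide on chance.

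Replicates of the libraries labelled knockout were far apart in the anti-PD-1 and LGG groups, with a biological coefficient of variation of 0.38 and 0.25 against 0.051 to 0.089 in wild type. Sequencing depth is argued against, since 0 of the 3 libraries that stand apart, at 28937315, 36421522 and 29854714 reads, lay outside the range of the other 21, from 24531528 to 49272593. A library or RNA quality difference may contribute, as the difference of anti-PD-1 replicates 3 and 2 followed transcript length (Spearman rho -0.511, an absolute value of 0.511, at an SD of 1.12), as did that of LGG replicate 2 and the mean of 1 and 3 (-0.637 at 0.667), and mitochondrial reads were 0.431% in anti-PD-1 replicate 3 and 1.21% in LGG replicate 2, against 1.33% to 2.5% in the others. Wild-type IgG pairs reached 0.397 at an SD of 0.287, so the factor of 2 set in advance was not met and this cannot be told apart from a difference between animals, which was not tested. A different mixture of cell types stays open only by the limit chosen after the result was seen. With the trend removed, 0 of 9 marker lists lay outside 95% of random lists in either group, which met the rules set in advance against a mixture. Some lists lay close to those bounds, however. Between anti-PD-1 replicates 3 and 2 the neutrophil, cytotoxic, T and B cell medians went from 1.63, 0.87, 0.81 and 0.66 to 0.45, 0.41, 0.37 and 0.48 (percentiles 90.8, 89.3, 96.4 and 75). In LGG replicate 2 the B cell list lay at 94.8.

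Y-linked transcripts were present in the 12 libraries labelled knockout, with Ddx3y at 1241 to 2136 normalised counts, and near 0 in the 12 wild-type libraries, with Ddx3y at 4.5 or lower, although the labels give female mice. A small share of male cells or reads is argued against, since the lowest ratio of Ddx3y to Ddx3x over those 12 libraries was 0.223 and the highest 0.348, a ratio near uniform across libraries. A candidate explanation is that these libraries come from male mice, since the 4 X-linked genes that escape inactivation had a median log2 difference of -0.78. Of these, Kdm6a was at -1.41 ± 0.12 and Ddx3x at -0.20 ± 0.11, which did not pass. If so, sex differs with genotype in each knockout against wild-type comparison and in each difference of a treatment effect between the genotypes, and their effects cannot be separated there.

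Among the 15 most abundant transcripts in wild-type IgG libraries, beside general and lysosomal genes such as Psap, Ftl1 and Eef1a1, were the macrophage genes Chil3, the highest at 698826 ± 12638 normalised counts and 2.57% of the total, Mmp12 at 181446 ± 6149 and Gpnmb at 140416 ± 3321. Itgax, which encodes CD11c, was at expression percentile 99, but bulk values cannot show whether the cells that express these macrophage genes carry it. By the rule set in advance, a minority of macrophage-type cells beside cDC1 and pDC is argued against. The pDC list had a median percentile of 24.7 and the cDC1 list 32.8, with Xcr1 at 4.39, Flt3 at 20.6, Clec9a at 27.7 and Zbtb46 at 38.8. An expression percentile does not measure a share of cells, so the test cannot exclude such a minority. The test left out the cDC2 and migratory dendritic cell lists, so it does not decide on a minority beside those cells. It remains a hypothesis that myeloid cells of the GM-CSF culture or macrophage type make up most of the wild-type IgG libraries. A list of 20 such genes, which excludes the genes above and shares Mrc1 with the macrophage list and Cd36 with the adipocyte list, had a median percentile of 97.6 there. The macrophage list was at 90.9, cDC2 at 86.6 and migratory dendritic cells at 90.6, so an activated dendritic cell of similar profile stays open and was not tested. Other groups had other profiles. With LGG in wild type the list of 20 was at 93.2, the macrophage list at 48.3, cDC2 at 43.6 and migratory dendritic cells at 97.6. Under IgG in the libraries labelled knockout the migratory list was at 59.8.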

How the results depend on the processing

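The alternatives that leave out the 3 libraries that stand apart or remove a length and GC trend were chosen after seeing the data, and the others were planned. Of 304 counts of genes or lists under settings other than leaving out 1 library, 237 stayed within 1.5 times and 67 moved. The cause was not tested, beyond what the fit itself implies for the wild-type counts named below. Over single genes, lists and other single values under such settings, 6937 kept direction and side of the threshold, 270 fell short of it, 193 newly passed, 71 moved and 1 reversed. With 1 library left out, these numbers were 6201, 319, 33, 100 and 1. Both reversals were of the list ribosomal_protein for the combination against LGG in knockout, lower at an adjusted p of 0.000579, and higher at 3.36e-07 with the 3 libraries left out and at 0.0208 without LGG replicate 2. Its call was lost with an estimated correlation (adjusted p = 0.743) and with array weights (0.0797). With 1 library left out its adjusted p ranged from 3.35e-11 to 0.0208. Below, WT and KO stand for genotype as labelled, P for anti-PD-1, L for LGG, PL for the combination, I for IgG and d for the difference between genotypes.

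Genes with a pseudocount of 8 numbered 7 in WT P-I; with TMM scaling, 16 in WT PL-L; with edgeR, 9 in WT P-I and 55 in KO PL-L. With a replicate block limma called 0 in WT P-I (1028 at an unadjusted p under 0.05 without the block) and 5 in WT PL-L. DESeq2 called 207 in WT P-I, 602 in KO P-I, 783 in d P-I, 81 in WT PL-L and 201 in KO PL-L. In a fit of the groups compared, limma called 1760 in WT P-I, 0 in KO P-I, 2677 in KO L-I, 7369 in KO PL-I, 1245 in KO PL-P, 7936 in KO-WT I, 1 in d P-I, 7388 in d PL-I, 145 in WT PL-L and 0 in KO PL-L (879 at an unadjusted p under 0.05 over all libraries, and 1992 in KO P-I). Fewer libraries estimate the variance there, but several counts rose, from 4 in WT P-I, 4267 in KO PL-I and 4977 in KO-WT I over all libraries. The fit over all libraries shares 1 variance per gene among groups of unequal spread. Their biological coefficient of variation was 0.38 in KO P and 0.25 in KO L, against 0.033 to 0.089 in the other groups. Leaving out the 3 libraries labelled knockout changes no wild-type mean. The rises to 1079 in WT P-I and 1095 in WT PL-L therefore came through the variance estimate. The cause of the other moves was not tested.

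With array weights, 3056 were called in WT P-I, 3053 in KO P-I, 9068 in KO L-I, 8210 in KO PL-I, 8535 in KO PL-P, 8769 in KO-WT I, 5112 in d P-I, 8949 in d L-I, 7952 in d PL-I, 8614 in d PL-P, 4680 in WT PL-L and 3656 in KO PL-L, with 12 lists each in KO P-I and d P-I. These weights were 8.4, 0.084 and 0.4 for replicates 1, 2 and 3 of KO L, and 2.3, 0.058 and 0.061 for those of KO P. The weighted means of both groups thus rest mostly on replicate 1. The default weights, which did not converge and reached a weight of 21703, called 4032 in WT P-I, 3 in KO P-I and 19 in d P-I. With the 3 libraries left out, 1079 were called in WT P-I, 1140 in KO P-I, 7830 in KO L-I, 7299 in KO PL-I, 8139 in KO-WT I, 2832 in d P-I, 8010 in d L-I, 7194 in d PL-I, 7239 in d PL-P, 1095 in WT PL-L and 1437 in KO PL-L, with 11 lists in KO P-I and 13 in d P-I. With the trend removed, 75 were called in WT P-I, 379 in KO P-I, 386 in d P-I, 79 in WT PL-L and 161 in KO PL-L, with 8 lists in d P-I. With an estimated correlation, lists numbered 0 in WT P-I and KO P-I, 8 in WT L-I and WT PL-I, 10 in KO L-I, 7 in KO PL-I, KO PL-P and KO-WT I, 3 in d P-I, 9 in d L-I, 6 in d PL-I and d PL-P and 2 in WT PL-L.

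With each library left out in turn, genes ranged from 0 to 3 in WT P-I, 6453 to 6566 in WT L-I, 6348 to 6421 in WT PL-I, 6588 to 6666 in WT PL-P, 74 to 4581 in KO P-I, 3352 to 4772 in KO L-I, 3477 to 3704 in KO PL-I, 3589 to 7544 in KO PL-P, 4053 to 4521 in KO-WT I, 8875 to 10008 in KO-WT over all treatments, 93 to 3830 in d P-I, 3974 to 5242 in d L-I, 3862 to 3972 in d PL-I, 4219 to 7264 in d PL-P, 0 to 7 in WT PL-L and 11 to 47 in KO PL-L. Lists ranged, in the same order, over 8 to 12, 12 to 13, 12 to 13, 12 to 12, 6 to 9, 13 to 17, 15 to 15, 13 to 15, 12 to 13, 15 to 16, 4 to 8, 15 to 17, 13 to 17, 13 to 13, 5 to 9 and 11 to 16, the 5 being without combination replicate 1. The Myd88 difference ranged from -0.987 to -0.856. Replicate numbers pair no libraries by the values: 0 of 11 comparisons had all 3 correlations over 0.1 (-0.43 to 0.52). At this depth and at the spread estimated over all libraries, simulated 1.5-fold changes were recovered in 33.3% of genes.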

Other observations

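The common scaling and flanking gene tests below were planned, and the draws of the splits were changed after first values were seen. The combination against LGG alone was added after the data were examined.

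Genes of the adipocyte marker list were lower with LGG in wild type and higher in the libraries labelled knockout under IgG (n = 3 per group). In wild type with LGG, Pparg, a regulator of lipid storage genes, went from 746.6 ± 56.5 to 37.9 ± 16.3 normalised counts, Lpl, a lipase gene, changed by -2.36 ± 0.13 on the log2 scale, the fatty acid receptor gene Cd36 by -1.57 ± 0.10 and Dhcr7, the last enzyme of cholesterol synthesis, by -2.84 ± 0.11. Of 4 adipocyte list genes 0 rose, 3 fell and 1 did not pass, also adjusted over the list alone (camera adjusted p = 0.00592). Of 19 cholesterol synthesis genes 1 rose, 10 fell and 8 did not pass, also adjusted over the list alone (adjusted p = 0.0197, and adjusted p = 0.21 with an estimated correlation). Under IgG the libraries labelled knockout had Pparg at 1.02 ± 0.20, Lpl at 0.88 ± 0.13, Cd36 at 1.10 ± 0.10 and Fabp4, a fatty acid binding protein gene, at 1.25 ± 0.27 above wild type, with 4 of 4 adipocyte list genes higher, also adjusted over the list alone (adjusted p = 0.00252). The cholesterol list was not called there, with 2 of 19 genes higher, 4 lower and 13 not past, also adjusted over the list alone (adjusted p = 0.636).

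Ifng, Gbp5, Irf8 and Arg2 also rose with LGG in wild type (n = 3 per group). Ifng, the interferon gamma gene, went from 936.9 ± 54.6 to 13829 ± 1095 normalised counts, the GTPase gene Gbp5 rose by 3.23 ± 0.19 on the log2 scale, the transcription factor gene Irf8 by 2.73 ± 0.05 and Arg2, the mitochondrial arginase, by 2.98 ± 0.15. Lists of other kinds were not called in wild type with LGG: Toll-like receptor signalling had 9 of 28 genes rise, 11 fall and 8 not pass (adjusted p = 0.974), MHC class II 2 of 13 rise, 4 fall and 7 not pass (adjusted p = 0.773), cDC1 markers 4 of 16 rise, 7 fall and 5 not pass (adjusted p = 0.339), and dissociation stress 12 of 21 rise, 5 fall and 4 not pass (adjusted p = 0.0845), each with the same counts when adjusted over the list alone. In the libraries labelled knockout, 7 of 13 pDC markers rose with LGG, 2 fell and 4 did not pass, with 8 higher and 2 lower when adjusted over the list alone (adjusted p = 0.0441, and adjusted p = 0.083 with an estimated correlation).

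The LGG response was smaller in the libraries labelled knockout, with a slope of 0.33 on that of wild type. The hypothesis that 1 common scaling could describe it for all gene lists is argued against, since 56.7% of the lists, 17 of 30, had a median residual outside 95% of random lists. Type I interferon genes lay above that scaling by a median of 0.77 and T cell markers by 1.68, and inflammatory genes at -0.23.

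Strain variation carried with the knocked-out allele could add differences near Myd88. Of 113 genes within 10 Mb, 26 (23%) differed over 2-fold between the genotypes, against 2234 of 12633 elsewhere (17.7%), an odds ratio of 1.39 (Fisher exact p = 0.139). With so few genes this cannot be told apart from no excess.

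Splits of 3 libraries against 3 number 10, too few for a share under 0.05. The real split gave 4 genes for anti-PD-1 against IgG in wild type (limma, highest other split 0, against 1028 genes at an unadjusted p under 0.05, 9 by edgeR and 207 by DESeq2 for the real split), and 1 of 10 splits was as large. The same held, with the highest other split at 0, for 7081 in LGG against IgG, 7010 in the combination against IgG and 7247 in the combination against anti-PD-1 in wild type. In the libraries labelled knockout the highest other was 0 for 4108 in LGG against IgG, for 4267 in the combination against IgG and for 35 in the combination against LGG, and 1 for 4673 in the combination against anti-PD-1. It was 0 for 4977 in knockout against wild type under IgG and 1 for 8 in the combination against LGG in wild type. For anti-PD-1 against IgG in the libraries labelled knockout, 2 of 10 splits gave at least the real 229, and the highest other, 4142, points to a structure of the samples. For knockout against wild type over the 4 treatments, 1 of 100 splits, the real one with 9149, was as large, a share under 0.05. The highest other gave 6705. These splits divide libraries, which the labels do not give as separate animals, so they do not decide on chance between animals.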
